A study of Canis lupus familiaris with 60 samples.

How the data were processed

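The intensity values used were the processed signals, per the file headers, of Agilent Feature Extraction 9.5.3.1: 1-colour (Cy3) scans of dog arrays with 44290 spots, 2256 of them controls, background-subtracted and detrended by the scanner software, without surrogate values, so that negative signals were kept. No normalization between arrays had been applied to them, per the file headers. The well-above-background, saturation and outlier marks were taken from the same deposited files. The deposited series values were found to be on a linear scale from the values themselves. No source used here states how they were made. Each of their columns has a median of 90 to 91, 97.0% of the values lie within 2% of quantile-normalized median spot intensities, and the lowest Spearman correlation with an array's own median spot signal was 0.9998. They were used only as an alternative. The genome build behind the probes is not given in the sources used here.

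Arm, wall and animal number come from the labels, as do the pacing schedule and the amount of RNA labelled, 0.4 ug. Whether the 2 arrays with the same arm and number come from the same animal was checked against the data: deviations from the group mean correlated with a median of 0.512 (range 0.0537 to 0.768) within an animal and −0.02 between animals, and for 24 of 30 animals the best partner was its own. The number 105 is borne by 1 non-failing and 1 CRT animal, whose deviations correlated at −0.179, and these were treated as different animals. Each array was on a slide of its own, so scan day, from the file headers, served as the batch. There were 8 scan days. Both arrays of an animal were scanned on the same day, and each day held more than 1 arm.

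The following were set before the data were examined: groups, comparisons, gene lists, thresholds and the alternatives, unless stated otherwise. Signals were divided by the 75th percentile of their array (median 62.2, range 19.0 to 105) and brought to the median percentile. Values under a floor of 5.92 were set to it, which applied to 7.06% of values, and log2 was taken. 368 spots marked as outliers by the scanner software were set to missing. A probe was kept if it was well above background on at least 9 of 60 arrays, the size of the smallest group, which left 29990 of 42034. Saturated probes numbered 2 to 21 per array and were kept.

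Comparisons were fitted with limma 3.58.1 in R 4.3.3, with the package data.table, version 1.17.8. Wall differences were taken within each animal and fitted over the 3 arms, and the levels of each wall were fitted separately, with moderated statistics and Benjamini-Hochberg adjustment over all kept probes of a comparison. Errors are standard errors of the fit or, where marked SD, standard deviations between animals. Permutation tests of means per animal were exact and two-sided. An array was doubted if its median Spearman correlation with the others lay more than 3 scaled median absolute deviations below the median.

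Probes were named from the gene number (9753 probes), symbol (722), synonym (306) or transcript accession (16) in the array's name column, using a table of dog genes on the assembly UU_Cfam_GSD_1.0 for names only, and 31237 had no name. Of the kept probes 8794 carried a symbol, for 8729 genes, and 59 genes had more than 1 kept probe. The genes printed are the largest named changes of each direction among those called, the called members of the lists that were largest, and a fixed set of genes often followed in heart failure. Some genes that this rule selects are not reported here. A gene not well above background on any array of a group is given as at least that many fold lower, from the lowest signal well above background on each array.

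The 30 gene lists covered fetal and wall stress genes, collagen and extracellular matrix, fatty acid oxidation, the tricarboxylic acid cycle, oxidative phosphorylation, glycolysis and glucose use, calcium handling, ion channels, sarcomere and cytoskeleton, immediate early genes, inflammatory genes, interferon and antigen presentation, adrenergic and angiotensin signalling, heat shock and unfolded protein response, cell cycle, apoptosis, hypoxia and angiogenesis, growth factors of the TGF-beta, BMP and IGF families, and markers of cardiomyocytes, fibroblasts, endothelium, smooth muscle and pericytes, macrophages, lymphocytes, erythroid cells, adipocytes, Purkinje cells, chamber endocardium, atrial myocytes, and nerve and Schwann cells. They were written from general knowledge. Each was tested with camera at a correlation between genes of 0.01, adjusted over the 30 lists of a comparison, and again with the correlation estimated from the data. A list counts as shifted by the first of these.

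Alternatives were quantile normalization, median scaling, normexp background correction (offset 50) with quantile normalization, the deposited series values, no filter, a stricter filter (21188 probes), scan day as a block, the animals of doubted arrays left out, array weights, trend and robust variance, only the arms compared, a fit of 60 arrays with and without the animal as replicate block (consensus correlation 0.447), and 1 probe per named gene. A floor of 2.96 and of 11.8, and the scan-day and doubted-array alternatives of the lists and named genes, were chosen after the data had been seen.

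The code was tested on simulated data: 50 of the 29990 probes were changed by each of 4 fold sizes in every comparison. Of 2-fold changes between 66% and 96% were recovered, of 3-fold changes between 94% and 100%, and false calls made up 0.741% to 7.69% of calls. A shift of 0.4 log2 put into oxidative phosphorylation genes was called, with 0 of the 29 other lists. The simulated probes varied independently of each other, and each arm was given the same spread. Recovery may be lower in an arm that varies more than the others. These tests therefore check the code and do not measure the false calls of probes or lists that arise when genes vary together.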

Results

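RNA was measured in the subendocardium, the inner layer of the left ventricular wall, of 30 dogs. Each heart gave 2 samples, 1 from the anterior wall, supplied by the left anterior descending artery, and 1 from the lateral wall, supplied by the left circumflex artery, and each sample was read on 1 single-colour array, so that there were 60 arrays. The 11 non-failing dogs were controls. In the 10 dogs with dyssynchronous heart failure (DHF) the left bundle branch, which conducts the impulse to the left ventricle, was ablated, and 1 week later pacing of the right atrium at 200 beats per minute began and lasted 6 weeks. In the 9 dogs with cardiac resynchronisation therapy (CRT) the ablation was followed by 3 weeks of the same atrial pacing and then by 3 weeks of pacing of both ventricles at the same rate, which restores near-simultaneous contraction of the walls. An array had between 15782 and 30497 of its 42034 probes well above background. The mean number per array was 25676 ± 2102 (SD, n = 11) in the non-failing anterior group, 25836 ± 2838 (n = 11) in the non-failing lateral group, 25921 ± 3432 (n = 10) in DHF anterior, 25266 ± 1616 (n = 10) in DHF lateral, 24673 ± 3081 (n = 9) in CRT anterior and 24213 ± 4693 (n = 9) in CRT lateral. The number of arrays limits the precision. 3 arrays correlated less with the others than the limit set beforehand, a median Spearman coefficient of 0.9144: the lateral array of dog CRT-294 (0.887), the lateral array of dog CRT-92 (0.912) and the lateral array of dog DHF-101 (0.9137). All levels below are log2 of the scaled signal, a wall difference is the lateral minus the anterior level of the same dog, and a probe is called when its Benjamini-Hochberg adjusted p from limma is under 0.05. The probes called in each of the 12 comparisons are plotted first.

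**Figure D1:**
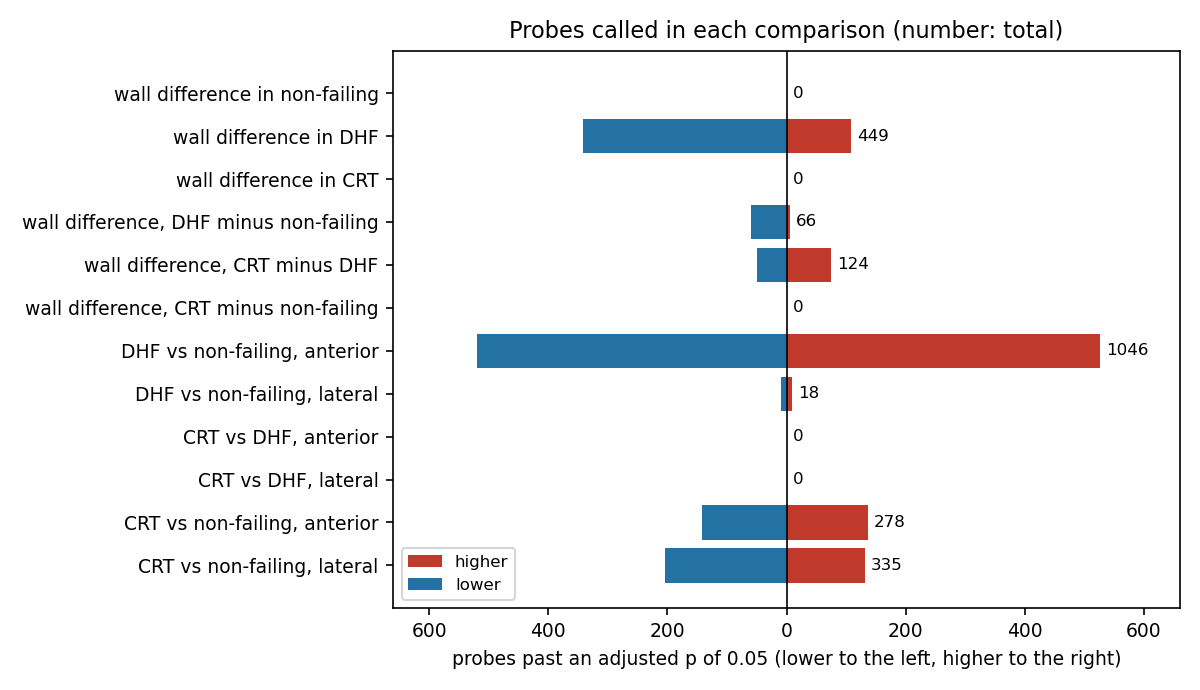
Probes called in each of the 12 comparisons, out of 29990 tested, with the number lower drawn to the left of 0 and the number higher to the right; the number beside each pair of bars is their total. The anterior wall of DHF against non-failing hearts gave 1046 probes and the lateral wall 18, and the walls of the same heart differed in DHF (449 probes) but gave 0 calls in the non-failing and CRT hearts.

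The first comparison asked whether the walls of a non-failing heart differ. The intercalated-disc protein XIRP2 had a wall difference of 0.25 ± 0.51 (SD, n = 11), the actin cross-linker FLNC 0.28 ± 0.38, the small heat shock protein CRYAB 0.12 ± 0.33 and the LIM-domain protein FHL1 0.19 ± 0.28. limma called 0 of 29990 probes, with a smallest adjusted p of 1, and 811 probes had an unadjusted p under 0.05. Scan day as a block also left 0 calls (smallest adjusted p 0.981), and 0 of the 30 gene lists shifted. In data simulated for this comparison the fit recovered 94% of probes changed 2-fold and 58% of those changed 1.5-fold.

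In the DHF hearts the lateral wall carried less RNA of many genes than the anterior wall of the same dog. THRSP, a regulator of lipid synthesis, was lower by the largest amount among the named genes called, at −1.54 (SE 0.27, 2.91-fold, adjusted p = 0.00294), and it was lower in 10 of 10 dogs. KIF23, a kinesin of dividing cells, followed at −1.34 (SE 0.27, adjusted p = 0.00659, 9 of 10 dogs), then the fast myosin heavy chain MYH1 at −1.26, the carotenoid-cleaving enzyme BCO2 at −1.18, the ubiquitin hydrolase UCHL1 at −1.16, the microtubule-associated protein MAP1A at −1.14 and XIRP2 at −1.12 (SE 0.18, adjusted p = 0.00139, 10 of 10 dogs). AZIN1 (−1.07), which stabilises ornithine decarboxylase, the growth factor TGFB2 (−1.05), the adhesion molecule VCAM1 (−1.05) and osteopontin, SPP1 (−1.01, adjusted p = 0.0391), were also lower. Fewer genes were higher in the lateral wall: the cadherin CDH7 at 1.44 (SE 0.29, 2.70-fold, adjusted p = 0.00663, 9 of 10 dogs), DHRS7C, an enzyme of the sarcoplasmic reticulum, at 1.04 (SE 0.18, adjusted p = 0.0029), the small GTPase RIT2 at 1.00, the poly(A)-binding protein PABPC1L at 0.97, the LIM-domain protein FHL2 at 0.90, the DNA glycosylase NEIL3 at 0.78, the receptor TNFRSF14 at 0.72 and PTGFR, the receptor for prostaglandin F, at 0.72 (SE 0.13, adjusted p = 0.00294, 10 of 10 dogs). XIRP2 stood at 9.04 ± 0.53 (SD, n = 10) in the anterior and 7.92 ± 0.72 in the lateral wall of DHF hearts, against 7.72 ± 0.40 (n = 11) and 7.97 ± 0.42 in non-failing hearts. PTGFR stood at 3.06 ± 0.43 in the anterior and 3.78 ± 0.40 in the lateral wall of DHF hearts, against 4.52 ± 0.74 and 4.32 ± 0.74 in non-failing hearts. It was well above background on 6 of the anterior and 7 of the lateral DHF arrays, MAP1A on 5 of 10 lateral, TGFB2 on 6 anterior and 2 lateral and NEIL3 on 5 anterior DHF arrays, so the sizes for these genes depend on the floor. RIT2 was higher in 8 and lower in 0 of 10 dogs, with a lowest difference of 0, as values at the floor in both walls give. Its size depends on the floor too.

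449 of 29990 probes were called in the DHF wall difference, 108 higher and 341 lower in the lateral wall, and 27 of them differed at least 2-fold, up to 6.79-fold. They included 188 named genes, 31 higher and 157 lower. Each dog's arrays were scanned on 1 of 8 days. Scan day as a block gave 420 calls, 364 of them shared, and on single days between 78.1% and 100% of the 449 probes had the sign of the mean. The count rested in part on single dogs: it was 185 without dog DHF-32, 222 without dog DHF-101 and 239 without dog DHF-16. It was 172 with the other arms left out of the fit and 0 in a fit of 60 arrays that ignored which arrays came from 1 dog, while normexp background correction together with quantile normalization gave 865, and quantile normalization alone 647. SPP1, HSPA2 and VWF lost their call without the dogs of poorly correlated arrays.

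By the lists fixed before the data were examined, 6 of the 34 measured sarcomere and cytoskeleton genes were lower in the lateral wall of DHF hearts and 0 higher, 10 of them lower when adjusted over the list alone. The list's median was −0.17 (camera adjusted p = 2.27e-05, and adjusted p = 0.592 with an estimated correlation). They were led by CRYAB at −0.88 (SE 0.12, adjusted p = 0.000495, 10 of 10 dogs), FLNC at −0.84, the ankyrin-repeat protein ANKRD23 at −0.74 and the laminin-binding integrin chain ITGA7 at −0.72. CRYAB stood at 13.61 ± 0.45 in the anterior and 12.74 ± 0.51 in the lateral wall (SD, n = 10). Of 23 heat shock and unfolded protein response genes 1 was called lower, HSPA2 at −0.42, and 5 when adjusted over the list alone. The list median was −0.20 (adjusted p = 8.38e-05, and adjusted p = 0.592 with an estimated correlation). Of 18 genes of glycolysis and glucose use PGM1, which links glycogen to glycolysis, was lower at −0.58 (9 of 9 dogs with a value), 6 were lower when adjusted over the list alone, and the list median was −0.25 (adjusted p = 0.00056, and adjusted p = 0.592 with an estimated correlation). FHL1 at −0.82 (10 of 10 dogs) and ANKRD1, a stretch-responsive repressor, at −0.59 (saturated on 1 of 10 anterior arrays) were the 2 of 8 fetal and wall stress genes called lower, 3 when adjusted over the list alone. The list median was −0.37 (adjusted p = 0.00751, and adjusted p = 0.407 with an estimated correlation). The 42 measured genes of oxidative phosphorylation had a median of 0.05, with 0 called (adjusted p = 0.00751, and adjusted p = 0.798 with an estimated correlation). With scan day as a block the adjusted p was 1.6e-05 for sarcomere genes, 0.00016 for heat shock genes, 0.000771 for glycolysis, 0.00348 for wall stress genes and 0.0322 for oxidative phosphorylation. The list mean kept its sign on 7 of 8 days for sarcomere and for wall stress genes, on 8 of 8 for heat shock and for glycolysis genes, and on 3 of 8 for oxidative phosphorylation. Without the dogs of the 3 poorly correlated arrays the wall stress list had an adjusted p of 0.0522 and oxidative phosphorylation 0.557. Markers of cardiac cell types shifted in 0 lists in this comparison. The endothelial list had a median of 0.06 (adjusted p = 0.391, and adjusted p = 0.798 with an estimated correlation), and 1 member, the clotting factor VWF, was called at 0.39 (10 of 10 dogs).

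**Figure D2:**
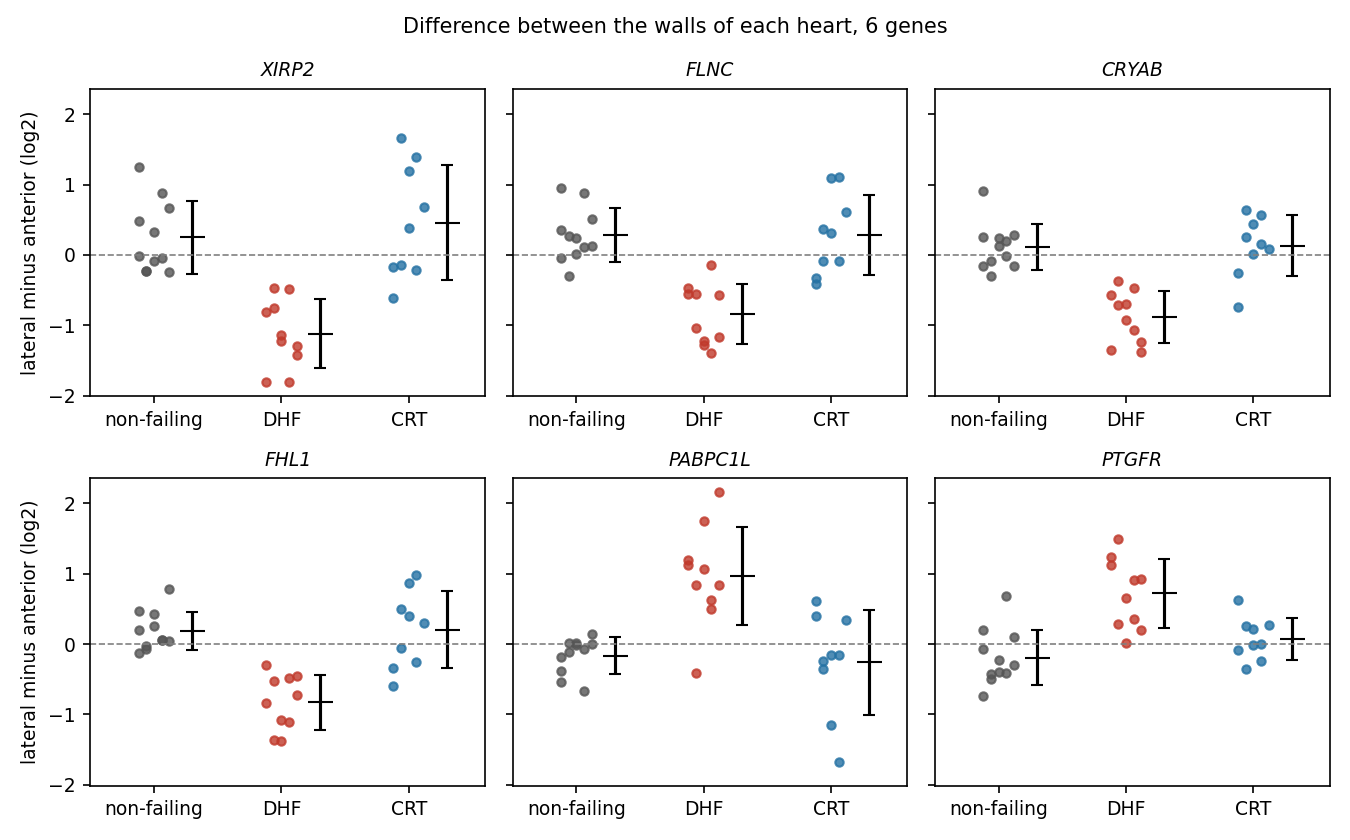
Lateral minus anterior log2 level of 6 genes in each dog (points) of the non-failing (n = 11), DHF (n = 10) and CRT (n = 9) arms, with the mean and SD beside them and a dashed line at 0. The DHF means are −1.12 for XIRP2, −0.84 for FLNC, −0.88 for CRYAB and −0.82 for FHL1, with 10 of 10 dogs below 0 for each, and 0.97 for PABPC1L and 0.72 for PTGFR, while the non-failing and CRT dogs lie on both sides of 0.

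A difference between arms needs its own test, so the wall differences themselves were compared. XIRP2 differed most among the named genes called lower, with a wall difference in DHF below that in non-failing hearts by a log2 value of −1.37 (SE 0.25, adjusted p = 0.0168, 10 of 10 DHF dogs below the non-failing mean). UCHL1 (−1.34), BCO2 (−1.28), MAP1A (−1.26) and FLNC (−1.12, SE 0.20, adjusted p = 0.0146) followed. In the other direction were PABPC1L at 1.13, NEIL3 at 1.05 and PTGFR at 0.91 (SE 0.18, adjusted p = 0.0202, 10 of 10 dogs). In all 66 probes were called, 6 higher and 60 lower, and 3228 had an unadjusted p under 0.05. The called probes held 38 named genes. Of 34 sarcomere genes 5 were called lower and 0 higher, 7 lower when adjusted over the list alone, among them CRYAB at −1.0 (SE 0.17, adjusted p = 0.00999), ANKRD23 at −0.93 and the integrin chain ITGB1 at −0.84. That list had a median of −0.16 (adjusted p = 0.000365, and adjusted p = 0.827 with an estimated correlation). The heat shock list had a median of −0.22 (adjusted p = 0.0014), glycolysis −0.27 (adjusted p = 0.0121), fetal and wall stress genes −0.50 (adjusted p = 0.0121), with FHL1 called at −1.01, and oxidative phosphorylation 0.10 (adjusted p = 0.0121). With an estimated correlation these had adjusted p = 0.827, adjusted p = 0.827, adjusted p = 0.551 and adjusted p = 0.91. In the fit with scan day as a block 50 probes were called, 41 of them shared, and UCHL1 (adjusted p = 0.0718), ITGB1 (0.0635) and PABPC1L (0.0876) were no longer among them. In that fit the lists had an adjusted p of 0.000185 for sarcomere genes (mean of the same sign on 6 of 7 days), 0.000526 for heat shock genes (5 of 7), 0.0145 for glycolysis (7 of 7), 0.0336 for wall stress genes (5 of 7) and 0.376 for oxidative phosphorylation (4 of 7). On the 7 days that held both arms between 81.8% and 100% of the 66 probes had the sign of the pooled difference. The count was 100 without the dogs of poorly correlated arrays, which ended the call of PABPC1L and left the wall stress list at an adjusted p of 0.0516 and oxidative phosphorylation at 0.509, and it ran from 0, in a fit of 60 arrays with no replicate block, to 372, with array weights, 131 of those higher and 241 lower.

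In the CRT hearts the walls of the same dog did not differ for any probe past the threshold. XIRP2 had a wall difference of 0.46 ± 0.81 (SD, n = 9), FLNC 0.29 ± 0.57, CRYAB 0.13 ± 0.43, PTGFR 0.08 ± 0.30 and THRSP 0.37 ± 1.30. limma called 0 of 29990 probes (smallest adjusted p 0.381), with 1059 at an unadjusted p under 0.05, and scan day as a block left 0 (smallest adjusted p 0.0743). 4 gene lists shifted, each with 0 members called over all probes. The 8 fetal and wall stress genes were each above 0 in the mean. Their median was 0.20 (adjusted p = 0.00899, and adjusted p = 0.178 with an estimated correlation). The 15 macrophage and myeloid markers had a median of −0.20 (adjusted p = 0.00156, and adjusted p = 0.199 with an estimated correlation), with 2 lower when adjusted over the list alone. Interferon and antigen presentation genes had a median of −0.11 (adjusted p = 0.00703, and adjusted p = 0.178 with an estimated correlation) and the 11 endothelial markers −0.07 (adjusted p = 0.0344, and adjusted p = 0.199 with an estimated correlation). Blocking by scan day gave an adjusted p of 0.00115 for wall stress genes (mean of the same sign on 6 of 8 days), 0.000143 for macrophage markers (7 of 8), 0.00115 for interferon genes (7 of 8) and 0.0128 for endothelial markers (6 of 8). Without the dogs of poorly correlated arrays, 2 of them CRT dogs, the adjusted p was 0.0594 for wall stress genes, 0.13 for macrophage markers, 0.0443 for interferon genes and 0.193 for endothelial markers.

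Set against DHF, the wall difference in CRT hearts was higher for some genes with a lateral level below the anterior level in DHF. KIF23, AZIN1 and MYH1, which had the same direction in DHF, did not pass. THRSP was higher by 1.91 (SE 0.40, 3.75-fold, adjusted p = 0.0273), XIRP2 by 1.58 (SE 0.27, adjusted p = 0.00591), MAP1A by 1.39, CCDC27 by 1.33 and TGFB2 by 1.29, each in 9 of 9 CRT dogs against the DHF mean. Lower were PABPC1L at −1.23 (SE 0.26, adjusted p = 0.0273, 9 of 9 dogs), DHRS7C at −1.18, the haemoglobin scavenger receptor of macrophages CD163 at −1.14, TNFRSF14 at −1.01 and the immediate early phosphatase DUSP1 at −0.96. VCAM1 differed by 1.22 and VWF by −0.66. 75 probes were called higher and 49 lower, and they held 47 named genes, 37 higher and 10 lower. The fit of 60 arrays with the dog as a replicate block called 48 probes, 44 higher and 4 lower, and the fit without non-failing dogs called 2. Of 34 sarcomere genes 4 were called higher, FLNC at 1.13, CRYAB at 1.01, ANKRD23 at 0.85 and ITGA7 at 0.78, and 10 were higher and 1 lower when adjusted over the list alone. That list had a median of 0.28 (adjusted p = 3.47e-05, and adjusted p = 0.347 with an estimated correlation). FHL1 at 1.03 was the 1 of 8 wall stress genes called, 3 when adjusted over the list alone. The list median was 0.57 (adjusted p = 0.000683, and adjusted p = 0.0785 with an estimated correlation). The medians were 0.16 for heat shock genes (adjusted p = 0.00455), −0.10 for oxidative phosphorylation (adjusted p = 0.00199), −0.22 for interferon genes (adjusted p = 0.00433) and −0.33 for macrophage markers (adjusted p = 0.00199), for which the estimated correlation gave adjusted p = 0.641, adjusted p = 0.673, adjusted p = 0.204 and adjusted p = 0.347. Scan day as a block gave 155 calls, 102 of them shared, without DHRS7C (adjusted p = 0.0631) and ANKRD23 (0.0581). On single days between 86.2% and 100% of these probes had the sign of the pooled difference. With that block the list adjusted p was 1.78e-05 for sarcomere genes (mean of the same sign on 7 of 8 days), 0.000104 for wall stress genes (8 of 8), 0.0116 for heat shock genes (7 of 8), 0.00314 for oxidative phosphorylation (5 of 8), 0.00169 for interferon genes (7 of 8) and 0.00134 for macrophage markers (8 of 8). When the dogs of poorly correlated arrays were left out 142 probes were called, 110 higher and 32 lower, and the adjusted p was 0.321 for oxidative phosphorylation and 0.0586 for macrophage markers. CD163, TNFRSF14, DUSP1, ANKRD23, VWF and HSPA2 then lost their call.

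The wall difference in CRT was not told apart from that in non-failing hearts at the level of single probes. XIRP2, FLNC and CRYAB had mean differences of 0.46, 0.29 and 0.13 in CRT and of 0.25, 0.28 and 0.12 in non-failing hearts. limma called 0 probes (smallest adjusted p 1, and 0.815 with scan day as a block) and 707 had an unadjusted p under 0.05. Data simulated for this comparison gave back 66% of 2-fold and 28% of 1.5-fold changes, so smaller differences stay open. 7 lists shifted with 0 members called. The macrophage list had a median of −0.18 (adjusted p = 9.13e-05), with 2 members lower when adjusted over the list alone, the hypoxia and angiogenesis list −0.09 (adjusted p = 0.0128), the tricarboxylic acid cycle list −0.12 (adjusted p = 0.0369), interferon genes −0.09 (adjusted p = 0.0369) and endothelial markers −0.14 (adjusted p = 0.0369). Purkinje and conduction system markers had a median of 0.19 (adjusted p = 0.0369) and atrial myocyte markers 0.26 (adjusted p = 0.0408). With an estimated correlation the 7 lists had, in the same order, adjusted p = 0.173, adjusted p = 0.376, adjusted p = 0.68, adjusted p = 0.276, adjusted p = 0.26, adjusted p = 0.173 and adjusted p = 0.182. In the fit with scan day as a block the adjusted p lay between 8.79e-06, for macrophage markers, and 0.0317, and the list mean kept its sign on 7 of 7 days for macrophage markers, 6 of 7 for the hypoxia, interferon and atrial lists, 5 of 7 for endothelial and Purkinje markers and 4 of 7 for the tricarboxylic acid cycle. Without the dogs of poorly correlated arrays the interferon (adjusted p = 0.063), endothelial (0.182), Purkinje (0.172) and atrial (0.181) lists no longer passed, and smooth muscle and pericyte markers did (0.0215, lower).

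The probes called in DHF were then followed in single dogs. For each DHF dog the probes were called from the wall differences of the other 9 DHF dogs, with the error of the fit drawn from the 3 arms, and each value was signed so that a positive wall difference points the way of the DHF lateral wall. This gave each DHF dog its own set of 185 to 558 probes. The CRT and non-failing dogs were measured on the 449 probes called from all DHF dogs. The mean signed wall difference was 0.50 ± 0.25 (SD, n = 10), above 0 in 10 of 10 DHF dogs. In CRT hearts it was −0.10 ± 0.31 (n = 9), above 0 in 3 dogs, and lower than in DHF by a difference of −0.60 (exact permutation p = 0.000227, two-sided). In non-failing hearts it was −0.06 ± 0.12 (n = 11), and CRT and non-failing hearts differed by −0.04 (exact permutation p = 0.692). In the anterior wall these probe sets departed from the non-failing mean by −0.69 ± 0.23 in DHF (n = 10) and by −0.31 ± 0.29 in CRT (n = 9), a difference of 0.38 (exact permutation p = 0.00694). In the lateral wall they departed by −0.12 ± 0.20 in DHF and by −0.35 ± 0.22 in CRT (n = 9), a difference of −0.23 (exact permutation p = 0.0272). The tests of CRT against DHF compare means over unlike probe sets, so a part of these differences may come from the probes.

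**Figure D3:**
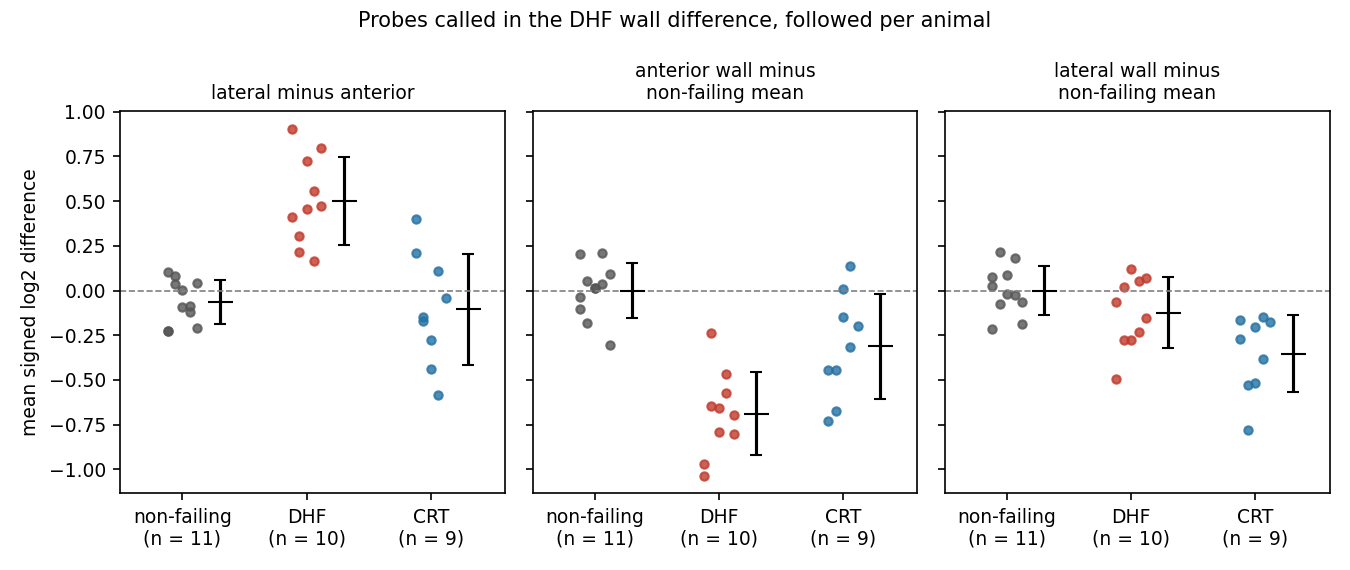
Mean signed log2 value, in each dog, of the probes called in the DHF wall difference, for the lateral minus anterior difference (left panel), the anterior wall minus the non-failing mean (middle) and the lateral wall minus the non-failing mean (right), with the mean and SD of each arm; the dashed line is 0 and DHF dogs are shown for probes called from the other 9. The 10 DHF dogs lie above 0 in the left panel, with a mean of 0.50, and below 0 in the middle panel, with a mean of −0.69.

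The next comparison asked what dyssynchronous failure changed in each wall. In the anterior wall the neurofilament chain NEFH was higher than in non-failing hearts by 2.50 (SE 0.38, 5.65-fold, adjusted p = 0.000238, 10 of 10 dogs), THRSP by 2.43, MYH1 by 2.20, the metallothionein MT2A by 1.78 (adjusted p = 0.0459), SPP1 by 1.77 and FHL1 by 1.75 (SE 0.21, adjusted p = 7.44e-06, 10 of 10 dogs). Connective tissue growth factor, CCN2, rose by 1.73 (SE 0.27, 3.31-fold, adjusted p = 0.000357), the phosphofructokinase PFKP by 1.69, the cystathionine lyase CTH by 1.63 and the growth-factor-binding protein IGFBP2 by 1.57. Among named genes called, the glutamate receptor subunit GRIA1 was lower by the largest amount, at −2.18 (SE 0.31, 4.53-fold, adjusted p = 6.99e-05, 10 of 10 dogs). CDH7 (−1.88), DHRS7C (−1.74), the interferon-induced EPSTI1 (−1.70), the adipocyte serine protease CFD (−1.55), the interferon-induced IFI44L (−1.51), CORIN (−1.47, SE 0.27, adjusted p = 0.00129), the protease that activates natriuretic peptides, PTGFR (−1.45), the interferon-induced GBP5 (−1.44), PABPC1L (−1.43) and the oxygenase FMO2 (−1.42) were also lower. GRIA1 and PTGFR were well above background on 6 and GBP5 on 5 of 10 DHF anterior arrays, and CTH on 6 of 11 non-failing anterior arrays. FGFBP1 was not well above background on any DHF anterior array and was at least 2.13-fold lower (adjusted p = 4.8e-08). ATP2A2, the calcium pump of the sarcoplasmic reticulum, fell by 0.82 (SE 0.13, adjusted p = 0.000554, 10 of 10 dogs), from 13.67 ± 0.26 (SD, n = 11) to 12.85 ± 0.21 (n = 10).

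Several genes often followed in heart failure did not pass the test in the DHF anterior wall. The natriuretic peptides NPPA and NPPB had differences of −0.08 (SE 0.20, adjusted p = 0.935) and 0.31 (SE 0.89, adjusted p = 0.945), the beta myosin heavy chain MYH7 of −0.04 (SE 0.16, adjusted p = 0.966) and phospholamban, PLN, of −0.00 (SE 0.18). The sign of MYH7 turned with scan day as a block (0.03), and that of PLN with median scaling (0.01) and with normexp and quantile normalization (0.00). The gap junction protein connexin 43, GJA1, had a difference of −0.56 (SE 0.19, adjusted p = 0.0952, 9 of 10 dogs). NPPB varied widely between dogs, at 10.93 ± 2.54 (SD, n = 10) in DHF and 10.62 ± 1.54 (n = 11) in non-failing anterior walls, and the difference between walls in DHF was −1.71 (SE 0.69, adjusted p = 0.263). CCN2 had a wall difference in DHF of −0.51 (adjusted p = 0.056) and ATP2A2 of 0.40 (adjusted p = 0.118). No kept probe could be named as MYH6.

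In all 1046 probes were called in the anterior wall, 526 higher and 520 lower, up to 34.8-fold, and they held 364 named genes, 210 higher and 154 lower. A block for scan day gave 1411 calls, 877 higher and 534 lower, 921 of them shared with the 1046. On the 7 days that held both arms between 88.2% and 99.3% of the 1046 probes had the sign of the pooled difference, and for NEFH, FHL1 and GRIA1 the within-day differences went the same way on 6, 7 and 7 of 7 days. MT2A (adjusted p = 0.0718), among the genes named above, did not pass with the block. NDUFB10 and IFIT2 lost their call without the dogs of poorly correlated arrays. Median scaling called 645 probes and array weights 1708.

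In the DHF anterior wall some genes of mitochondrial energy metabolism were called lower and some genes of glucose use higher, and none of these lists passed with an estimated correlation. Of 42 oxidative phosphorylation genes 5 were called lower and 0 higher, 11 lower when adjusted over the list alone. The list as a whole had a median of −0.27 (adjusted p = 8.73e-11, and adjusted p = 0.349 with an estimated correlation). The complex I subunits NDUFB10 (−0.71), NDUFV2 (−0.65, SE 0.11, adjusted p = 0.000866) and NDUFS7 (−0.54) and the ATP synthase subunit ATP5PO (−0.54) led them. Of 20 tricarboxylic acid cycle genes IDH3B (−0.67) and SDHB (−0.54) were called lower, 4 when adjusted over the list alone. The median was −0.23 (adjusted p = 0.000306, and adjusted p = 0.575 with an estimated correlation). Of 18 glycolysis and glucose use genes 6 were called higher, 7 when adjusted over the list alone. The median of the list was 0.18 (adjusted p = 0.000223, and adjusted p = 0.389 with an estimated correlation). PFKP, the glucose transporter SLC2A1 (1.13, 2.19-fold, 10 of 10 dogs), the hexokinase HK1 (0.75) and PDK1 (0.75), a kinase that inhibits pyruvate dehydrogenase, came first. With scan day as a block these lists had an adjusted p of 8.89e-08, 0.00632 and 2.26e-05, and their means kept their signs on 6, 6 and 7 of 7 days. NDUFB10 did not pass with that block (adjusted p = 0.0881).

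Some sarcomere and stress-protein genes were called higher in the same wall and some interferon genes lower, and again no list passed with an estimated correlation. Of 34 sarcomere and cytoskeleton genes 7 were called higher and 0 lower, 9 higher when adjusted over the list alone, led by CRYAB (1.13, SE 0.20, adjusted p = 0.000984), the M-band protein MYOM1 (0.94), FLNC (0.91) and ITGA7 (0.91). The list median was 0.08 (adjusted p = 0.0352, and adjusted p = 0.756 with an estimated correlation). Of 23 heat shock genes 4 were called higher, among them HSPB8 (0.78), HSPA4 (0.75) and HSPB7 (0.60), and 6 when adjusted over the list alone. The median was 0.20 (adjusted p = 0.000208, and adjusted p = 0.502 with an estimated correlation). Of 20 immediate early genes IER3 (0.93) and BTG2 (0.75) were higher. Their median was 0.14 (adjusted p = 0.0166, and adjusted p = 0.349 with an estimated correlation). Of 18 interferon and antigen presentation genes 5 were called lower, 8 when adjusted over the list alone. The interferon list had a median of −0.61 (adjusted p = 6.45e-07, and adjusted p = 0.349 with an estimated correlation). IFI44L, the proteasome subunit PSMB8 (−1.28), the peptide transporter TAP2 (−0.95) and IFIT2 (−0.84, well above background on 5 of 10 DHF arrays) were among them. Markers of other cell types moved too: of 11 endothelial markers EGFL7 was called lower (−0.92) and 4 when adjusted over the list alone. The endothelial median was −0.18 (adjusted p = 0.0113, and adjusted p = 0.349 with an estimated correlation). Of 6 adipocyte markers CFD was called lower, 3 when adjusted over the list alone. The adipocyte median was −0.37 (adjusted p = 0.00586, and adjusted p = 0.227 with an estimated correlation). Blocked by scan day, these 6 lists had an adjusted p of 0.00632, 2.26e-05, 0.0649, 2.53e-06, 0.0252 and 0.0011, in the order above, and their means kept their signs on 6, 6, 5, 6, 5 and 7 of 7 days. In that fit PSMB8 (adjusted p = 0.0544), IFIT2 (0.0699) and EGFL7 (0.0534) did not pass. The immediate early list had an adjusted p of 0.065 without the dogs of poorly correlated arrays.

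In the DHF lateral wall 3 named genes were called. NEFH was higher by 2.37 (SE 0.32, 5.17-fold, adjusted p = 0.000422, 10 of 10 dogs), EGFL7 lower by a log2 value of −0.98 (SE 0.19, adjusted p = 0.0395, 10 of 10 dogs) and C9H17orf75 at −0.84 (SE 0.17, adjusted p = 0.0395, 10 of 10 dogs). CCN2 (1.02, adjusted p = 0.135, 9 of 10 dogs) and ATP2A2 (−0.33, adjusted p = 0.624) did not pass. Oxidative phosphorylation genes had a median of −0.17 (adjusted p = 0.000161, and adjusted p = 0.609 with an estimated correlation) with 0 called, the tricarboxylic acid cycle −0.20 (adjusted p = 0.000415, and adjusted p = 0.594 with an estimated correlation) and interferon genes −0.58 (adjusted p = 2.43e-06, and adjusted p = 0.192 with an estimated correlation), 6 of these lower when adjusted over the list alone. Immediate early genes had a median of 0.19 (adjusted p = 0.000415, and adjusted p = 0.109 with an estimated correlation). Endothelial markers had a median of −0.35 (adjusted p = 0.0349, and adjusted p = 0.29 with an estimated correlation) and adipocyte markers −0.48 (adjusted p = 0.0134, and adjusted p = 0.109 with an estimated correlation). With scan day as a block the adjusted p lay between 3.1e-05, for interferon genes, and 0.0274, for endothelial markers, and the list means kept their signs on 5 of 7 days for immediate early genes, 7 of 7 for adipocyte markers and 6 of 7 for the others.

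18 probes were called in the lateral wall, 9 higher and 9 lower, and 2438 had an unadjusted p under 0.05. The fit blocked by scan day gave 18 calls, 5 higher and 13 lower, 10 of them shared, without EGFL7 (adjusted p = 0.0963), which also lost its call without the dogs of poorly correlated arrays, and on single days between 77.8% and 100% of the 18 probes had the sign of the pooled difference. The small count moved with the setting: the fit of 60 arrays with the dog as a replicate block called 142, 54 higher and 88 lower. Quantile normalization called 44 (17 higher, 27 lower), median scaling 6 (4 and 2), normexp with quantile normalization 46 (10 and 36) and the deposited series values 48 (10 and 38). Whether DHF changed the walls unequally is tested by the wall differences above, which were called for 66 probes.

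Within a single wall no probe separated CRT from DHF. limma called 0 probes in the anterior wall (smallest adjusted p 0.188, with 1267 at an unadjusted p under 0.05) and 0 in the lateral wall (smallest adjusted p 1, with 942), and scan day as a block left 0 in each, with smallest adjusted p of 0.139 and 0.639. The anterior wall gave 2 calls, both lower, without the dogs of poorly correlated arrays. NPPB in the lateral wall had a difference of 2.44 (SE 0.80, adjusted p = 1, higher in 8 of 9 dogs), ATP2A2 in the anterior wall of 0.39 (adjusted p = 1) and CCN2 of −0.56 in the anterior (adjusted p = 1) and 0.16 in the lateral wall (adjusted p = 1). In simulated data of these comparisons 80% of 2-fold changes were recovered in each wall, and of 1.5-fold changes 22% in the anterior and 16% in the lateral wall.

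Gene lists, which pool small shifts, differed between CRT and DHF mostly in the lateral wall, with 0 members called over all probes. There the 8 fetal and wall stress genes were each higher in the mean, 2 of them when adjusted over the list alone. These 8 genes had a median of 0.40 (adjusted p = 8.21e-06, and adjusted p = 0.0424 with an estimated correlation). Sarcomere genes had a median of 0.22 (adjusted p = 8.28e-06, and adjusted p = 0.312 with an estimated correlation), with 2 of 34 higher when adjusted over the list alone, glycolysis genes 0.16 (adjusted p = 0.0391, and adjusted p = 0.674 with an estimated correlation) and cardiomyocyte markers 0.21 (adjusted p = 0.0391, and adjusted p = 0.643 with an estimated correlation). Macrophage and myeloid markers had a median of −0.38 (adjusted p = 8.28e-06, and adjusted p = 0.136 with an estimated correlation), endothelial markers −0.24 (adjusted p = 0.00429, and adjusted p = 0.136 with an estimated correlation) and interferon genes −0.17 (adjusted p = 0.00791, and adjusted p = 0.643 with an estimated correlation). In the anterior wall the oxidative phosphorylation list had a median of 0.08 (adjusted p = 0.0226, and adjusted p = 0.925 with an estimated correlation). The block for scan day gave an adjusted p of 3.13e-07 for wall stress genes, 3.34e-07 for sarcomere genes, 0.0149 for glycolysis, 0.0048 for cardiomyocyte markers, 1.26e-05 for macrophage markers, 0.00913 for endothelial markers, 0.00603 for interferon genes and 0.00424 for anterior oxidative phosphorylation. The mean of the same sign was seen on 7 of 8 days for the first 4 of these, 5 of 8 for macrophage markers and 6 of 8 for the others. Without the dogs of poorly correlated arrays the glycolysis (adjusted p = 0.726), endothelial (0.0817), interferon (0.204) and anterior oxidative phosphorylation (0.867) lists no longer passed. In the same fit collagen and matrix genes (0.00458, lower) and immediate early genes (0.0346, higher) in the lateral wall and heat shock genes (0.0369, lower) in the anterior wall passed.

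The last comparisons set CRT against non-failing hearts. In the CRT anterior wall NEFH was higher by 2.62 (SE 0.40, 6.16-fold, adjusted p = 0.000459, 9 of 9 dogs), MYH1 by 1.90 and PFKP by 1.49. GRIA1 was lower at −1.80 (SE 0.32, 3.48-fold, adjusted p = 0.00376, 9 of 9 dogs), CFD at −1.54, the collagen COL28A1 at −1.38 and the myosin-binding protein MYBPC3 at −1.30 (adjusted p = 0.0449). GRIA1 was well above background on 6 of 9 CRT arrays. CCN2 was higher by 1.16 (adjusted p = 0.0353) and FHL1 by 1.36. Glycolysis genes had a median of 0.22, with PFKP and SLC2A1 (0.97) called and 5 of 18 higher when adjusted over the list alone (adjusted p = 0.000294, and adjusted p = 0.49 with an estimated correlation). Immediate early genes had a median of 0.29 (adjusted p = 0.000121, and adjusted p = 0.0898 with an estimated correlation), with DUSP1 (0.97) and IER3 (0.83) called, and heat shock genes 0.17 with 0 called and 3 of 23 higher when adjusted over the list alone (adjusted p = 0.0152, and adjusted p = 0.783 with an estimated correlation). Oxidative phosphorylation had a median of −0.17 with 0 called and 3 lower when adjusted over the list alone (adjusted p = 8.92e-06, and adjusted p = 0.723 with an estimated correlation), the tricarboxylic acid cycle −0.10 (adjusted p = 0.0375, and adjusted p = 0.873 with an estimated correlation) and interferon genes −0.50, with 6 of 18 lower when adjusted over the list alone (adjusted p = 7.97e-07, and adjusted p = 0.232 with an estimated correlation). Endothelial markers, with EGFL7 called at −1.16, had a median of −0.35 (adjusted p = 0.00601, and adjusted p = 0.26 with an estimated correlation) and adipocyte markers −0.23 (adjusted p = 0.0216, and adjusted p = 0.232 with an estimated correlation).

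278 probes were called in the CRT anterior wall, 142 of them lower and the others higher. They held 52 named genes that were higher and 43 that were lower. Blocking by scan day gave 579 calls, 418 higher and 161 lower, 233 of them shared, and on the 7 days with both arms between 76.3% and 99.3% of the 278 had the sign of the pooled difference. MYBPC3 did not pass with that block (adjusted p = 0.0594). Normexp with quantile normalization gave 182 higher and 312 lower, and the deposited series values 174 higher and 302 lower. Leaving out the dogs of poorly correlated arrays left 146 calls, without MYH1, CCN2, SLC2A1, DUSP1 and EGFL7. Median scaling gave 137 calls and no filter 148. The block gave an adjusted p of 4.17e-06 for glycolysis, 0.00386 for immediate early genes, 0.000838 for heat shock genes, 0.00391 for oxidative phosphorylation, 0.549 for the tricarboxylic acid cycle, 9.49e-07 for interferon genes, 0.00855 for endothelial and 0.00565 for adipocyte markers. The list means kept their signs on 7, 7, 6, 5, 4, 6, 6 and 6 of 7 days in that order. The heat shock list had an adjusted p of 0.147 without those dogs.

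In the CRT lateral wall NEFH was again higher, by 2.40 (SE 0.33, 5.27-fold, adjusted p = 0.000152, 9 of 9 dogs), followed by the taurine transporter SLC6A6 at 2.11, CTH, well above background on 4 of 11 non-failing lateral arrays, at 1.94 and SPP1 at 1.79. CD163 was lower at −2.08 (SE 0.39, 4.22-fold, adjusted p = 0.00612, 9 of 9 dogs), the stem cell factor KITLG at −1.78, the interferon-induced GBP6 at −1.71 and EPSTI1 at −1.64, and the complement subunit C1QA at −1.61. CD163 stood at 6.26 ± 0.62 (SD, n = 11) in non-failing and 4.18 ± 1.10 (n = 9) in CRT lateral walls, and was well above background on 6 of the 9 CRT arrays. Of 15 macrophage and myeloid markers CD163 and C1QA were called lower, 6 when adjusted over the list alone. The macrophage median was −0.37 (adjusted p = 8.3e-05, and adjusted p = 0.168 with an estimated correlation). Of 11 endothelial markers EGFL7 (−1.40, SE 0.20, adjusted p = 0.000268) and the angiopoietin receptor TEK (−1.39) were called lower, 5 when adjusted over the list alone. The endothelial list had a median of −0.40 (adjusted p = 6.42e-05, and adjusted p = 0.0455 with an estimated correlation). Of 18 interferon and antigen presentation genes 4 were called lower, IFI44L (−1.38), PSMB8 (−1.29), TAP2 (−1.0) and IFI6 (−0.88), 11 when adjusted over the list alone. Interferon genes had a median of −0.82 (adjusted p = 8.04e-10, and adjusted p = 0.0455 with an estimated correlation). Each of the 20 immediate early genes was higher in the mean, 1 called, IER3 (0.87). The median over them was 0.28 (adjusted p = 6.42e-05, and adjusted p = 0.0455 with an estimated correlation). Oxidative phosphorylation genes had a median of −0.19 (adjusted p = 7.51e-06, and adjusted p = 0.634 with an estimated correlation), the tricarboxylic acid cycle −0.23 (adjusted p = 0.000413, and adjusted p = 0.642 with an estimated correlation), glycolysis genes 0.19, with PFKP (1.59) and ENO1 (0.63) called (adjusted p = 0.0303, and adjusted p = 0.79 with an estimated correlation), and adipocyte markers −0.32, with CFD called at −1.38 (adjusted p = 0.0493, and adjusted p = 0.128 with an estimated correlation).

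335 probes were called in the CRT lateral wall, 131 higher and 204 lower, holding 54 named genes that were higher and 60 that were lower. The fit of 60 arrays with the dog as a replicate block called 723, 278 higher and 445 lower, and the deposited series values gave 127 higher and 316 lower. Median scaling called 188 and no filter 198. Scan day as a block gave 425 calls, 200 higher and 225 lower, without IFI6 (adjusted p = 0.0731), and on single days between 90.7% and 98.8% of the 335 had the sign of the pooled difference. With that block the adjusted p was 1.22e-05 for macrophage markers, 8.1e-05 for endothelial markers, 6.29e-09 for interferon genes, 0.0015 for immediate early genes, 3.26e-05 for oxidative phosphorylation, 0.00318 for the tricarboxylic acid cycle, 0.00722 for glycolysis and 0.0151 for adipocyte markers. The list means kept their signs on 7, 7, 6, 6, 4, 4, 5 and 7 of 7 days in that order. With the dogs of poorly correlated arrays left out the glycolysis (adjusted p = 0.245) and adipocyte (0.0974) lists no longer passed, and GBP6, EPSTI1, ENO1, IFI6 and TEK lost their call.

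How far CRT hearts departed from non-failing hearts along with DHF hearts was measured over all 29990 probes, in comparisons that share an arm and so share its chance values. In the anterior wall the changes in DHF and in CRT against the same controls had a covariance of 0.06, against a mean of 0.0193 and a range of −0.000767 to 0.0509 in 100 draws simulated with no effect. It was 0.0447 ± 0.00447 (SD over 50 halvings) when each used its own part of the controls. In the lateral wall the covariance was 0.0553, which lies inside the simulated range of 0.000496 to 0.0672, and 0.0374 ± 0.00549 with the controls split. The DHF change and the CRT minus DHF change had covariances inside the simulated ranges in each wall: −0.0225 in the anterior (−0.0572 to −0.0016) and −0.0101 in the lateral wall (−0.0834 to 0.00356), and −0.00116 ± 0.0114 and 0.0178 ± 0.0125 with the DHF dogs split. For the wall difference the same pair had a covariance of −0.0529 (r = −0.752), also inside the simulated range of −0.0642 to 0.0028, and −0.0294 ± 0.00531 with the DHF dogs split. The wall differences DHF minus non-failing and CRT minus non-failing had a covariance of 0.0129, inside 0.00341 to 0.054, and −0.00661 ± 0.00669 split. Unsplit, the covariances after the first were not told apart from what a shared arm gives by chance. With the arm split, the lateral covariance of DHF and CRT changes was positive in every halving (0.0256 to 0.0469). That of the DHF and the CRT minus DHF change in wall difference was negative in every halving (−0.0386 to −0.00997). The split values share no dogs of that arm. They do not exclude that a shared arm together with chance gave the unsplit values, which lay inside the simulated ranges. The other split covariances after the first took both signs. Halvings reuse the same dogs and no range without effect was simulated for split values, so chance was not excluded. These are covariances across probes, which are not independent replicates.

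Calls made in 5 DHF dogs were also measured in separate animals. In 34 of 50 halvings at least 10 anterior probes were called. For these the mean change in the called direction was 1.08 ± 0.32 (SD over halvings) in the other 5 DHF dogs. It was 0.91 ± 0.22 in the CRT dogs, 84.7% of the DHF value, and below it in 29 of the 34 halvings. Both were measured against the same controls, those not used for calling, and share their chance values. The median number of calls was 47.5, so the share applies to these few probes and not to DHF changes in general. For the lateral wall 1 halving gave at least 10 calls, with 13, too few to compare. Of the 526 probes higher and 520 lower in the DHF anterior wall, 103 and 80 were called the same way in the CRT anterior wall, where lists independent of each other would share 2.39 and 2.46. The simulated and split values above show how much shared controls contribute, and part of this overlap may come from them. NEFH, PFKP and GRIA1 were among the genes called in both.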

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

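The test of marker means relative to fibroblast and smooth muscle markers was chosen after the result was seen, and the other tests in this part were set beforehand.

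The walls of DHF hearts differed by 449 probes. Of the sarcomere genes called, CRYAB and FLNC had the lateral level furthest below the anterior one. Against non-failing hearts both were higher in the anterior wall. If brighter or dimmer arrays of 1 wall made the difference, a covariate for brightness would remove it, but 98.9% of the mean signed difference stayed, with 405 probes called. If the mix of cells differed between the walls, covariates for 4 marker means would remove it, and 89.9% stayed, though 162 of the 449 probes kept their call with the 4 covariates. Neither accounts for most of the difference, and its mechanism was not tested. In 100 assignments of sign to the dogs, the real one included, 1 gave as many calls, with 312, from turning 1 dog, as the highest other.

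More probes differed from non-failing hearts in the anterior (1046) than in the lateral wall (18) of DHF hearts, with FHL1 and GRIA1 among those called in the anterior wall. A larger spread between lateral arrays could lower the lateral count, but the anterior fold changes with the lateral standard errors still gave 644 calls. The lateral fold changes with the anterior standard errors gave 128, so that spread may account for a part of the gap. A few poor lateral arrays could do the same, and without their dogs the lateral wall had 14 calls. The direct test, the wall difference of DHF minus non-failing, had 66 calls. Of the 1046 anterior probes 93.2% had the same sign in the DHF lateral wall. The median lateral change was 0.525 of the anterior one. These probes were picked by their anterior change and both walls come from the same dogs, so chance values are shared and no value for unchanged lateral walls was available. Whether the other anterior changes are absent or only smaller in the lateral wall was thus not settled.

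Endothelial markers, macrophage markers and interferon genes, among them EGFL7, CD163 and IFI44L, were lower in the lateral wall of CRT than of non-failing hearts. Poorly correlated arrays, 2 of them in this group, could lower dim genes, but without their dogs 3 of 3 lists still passed. Dimness was not tested by this, since arrays were left out by correlation and not by brightness. The lateral array of CRT-92, left out, had a 75th percentile of 57.5, and that of CRT-104, kept, had 27.4. With an estimated correlation the endothelial and interferon lists passed (adjusted p = 0.0455 for each) and the macrophage list did not (adjusted p = 0.168). A lower share of all non-myocyte cells would lower fibroblast and smooth muscle markers alike, and relative to these the endothelial mean was lower by a log2 value of −0.343 and the macrophage mean by −0.367, the larger exact permutation p being 0.0293. The endothelial and macrophage lists may thus reflect fewer of these cells or lower expression in them, which arrays of whole tissue do not separate. The fibroblast and smooth muscle means themselves differed by −0.278 and −0.082 (exact permutation p = 0.22 and 0.356). Interferon genes were not set against other markers, so the cells behind their lower level were not tested.

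Whether chance can be excluded was asked with 100 regroupings of each comparison, the real one included. As many probes as in the real grouping were called in 1 of 100 for DHF minus non-failing wall differences (66, highest other 2), CRT minus DHF (75 higher and 49 lower, highest other 9), DHF anterior (1046, highest other 1), CRT anterior (278, highest other 4) and CRT lateral (335, highest other 2). For the DHF lateral wall, where NEFH was called, it was 2 of 100 (18, highest other 28). For the comparisons with 0 calls it was 100 of 100 by construction, with highest others of 694 in non-failing walls, 2 in CRT walls, 1 for CRT minus non-failing wall differences, 22 for CRT against DHF anterior and 2 for lateral. The regrouping with 694 turned the sign of 8 of 11 dogs and kept each of 7 scan days whole on 1 side, which is consistent with wall differences that vary by scan day; with scan day as a block the real grouping had 0.

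Single dogs lay far from the rest in 12 of 167 groups of values tested, where chance alone marks about 1 in 20. In wall differences of DHF hearts these were AZIN1 at −3.67 (dog DHF-16, nearest −1.41), PGM1 at −1.62 and ITGB1 at 0.4 (DHF-152), and SPP1 at 1.59, NPPB at 5.4 and CCDC27 at 0.83 (DHF-53). In levels they were MT2A at 11.14 (DHF-136, nearest 7.77), SPP1 at 8.93 (DHF-53) and ATP2A2 at 12.31 (DHF-101) in DHF anterior walls, FGFBP1 at 3.25 in a CRT anterior wall (CRT-124) and GBP6 at 4.35 and TEK at 2.58 in a CRT lateral wall (CRT-294). Dog DHF-53 accounts for 4 of the 12.

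The difference between arms was itself tested for wall differences. DHF minus non-failing gave 6 probes higher and 60 lower, with XIRP2 −1.37, UCHL1 −1.34, BCO2 −1.28, MAP1A −1.26, FLNC −1.12, TGFB2 −1.02, FHL1 −1.01, CRYAB −1, ANKRD23 −0.93, ITGB1 −0.84, PABPC1L 1.13, NEIL3 1.05 and PTGFR 0.91. CRT minus DHF gave 75 higher and 49 lower, with THRSP 1.91, XIRP2 1.58, MAP1A 1.39, CCDC27 1.33, TGFB2 1.29, VCAM1 1.22, FLNC 1.13, FHL1 1.03, CRYAB 1.01, ANKRD23 0.85, ITGA7 0.78, PABPC1L −1.23, DHRS7C −1.18, CD163 −1.14, TNFRSF14 −1.01, DUSP1 −0.96 and VWF −0.66.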

How the results depend on the processing

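The floor alternatives, and scan day and doubted arrays for the lists and named genes, were chosen after the results were seen; the others were set beforehand. Of the counts and other leading results under alternatives, 145 stayed within a fixed ratio or spread of the result used and 63 moved. Counts that stayed include 449 against 647 for the DHF wall difference with quantile normalization. They also include comparisons with 0 calls that stayed at 0. Among the comparisons that had calls, more of the alternative counts moved than stayed. In what follows the numbers are called probes, and the cause of each move was not tested unless stated. A count written as 2.7e2 is rounded to 2 digits.

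The wall difference in DHF, 449 with the settings used, was 231 with median scaling, 865 with normexp together with quantile normalization (normexp in what follows), 806 with the deposited series values, 836 with array weights, 172 with only the arm compared, 272 genes with 1 probe per named gene and 0 in the fit of 60 arrays with no replicate block, which by construction leaves the spread between dogs in the error. The wall difference of DHF minus non-failing hearts, 66, was 188 with quantile normalization, 34 with median scaling, 317 with normexp, 2.7e2 with the series values, 1.5e2 with the stricter filter, 100 without the dogs of doubted arrays, 372 with array weights, 40 with trend and robust variance, 196 with only the arms compared, 0 with no replicate block, 103 with 1 probe per gene and 126 with the floor doubled. For CRT minus DHF, 75 higher and 49 lower, the totals were 266 with quantile normalization, 20 with median scaling, 417 with normexp, 364 with the series values, 67 with no filter, 189 with the stricter filter, 396 with array weights, 70 with trend and robust variance, 2 with only the arms compared, 48 with the replicate block, 0 with no replicate block and 74 with 1 probe per gene.

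In the anterior wall DHF against non-failing hearts, 1046, gave 645 with median scaling, 1708 with array weights and 441 with 1 probe per gene. In the lateral wall, 18, it gave 44 with quantile normalization, 6 with median scaling, 46 with normexp, 48 with the series values, 6 with no filter, 36 with the stricter filter, 120 with array weights, 46 with only the arms compared, 142 with the replicate block, 88 with no replicate block, 3 with 1 probe per gene and 8 with the floor halved. CRT against DHF in the anterior wall, 0, gave 2 without the dogs of doubted arrays. CRT against non-failing hearts in the anterior wall, 278, gave 137 with median scaling, 494 with normexp, 476 with the series values, 148 with no filter, 579 with scan day as a block, 146 without the dogs of doubted arrays, 462 with array weights and 1.2e2 with 1 probe per gene. In the lateral wall, 335, it gave 188 with median scaling, 198 with no filter, 517 with array weights, 723 with the replicate block, 525 with no replicate block and 1.2e2 with 1 probe per gene.

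Of the tests of 30 lists in 12 comparisons 66 passed, 62 with quantile normalization, 75 with scan day as a block, 49 without the dogs of doubted arrays and 4 with an estimated correlation. The 4 were wall stress genes in CRT against DHF lateral walls and immediate early, interferon and endothelial genes in CRT against non-failing lateral walls. Lists that passed only with scan day as a block were, in CRT wall differences, the tricarboxylic acid cycle (adjusted p = 0.016), oxidative phosphorylation (0.032), sarcomere genes (0.0429) and hypoxia genes (0.0429), and in CRT minus non-failing wall differences oxidative phosphorylation (0.0405). They were also cell cycle genes in DHF lateral walls (0.0274), the tricarboxylic acid cycle (0.0239) in CRT against DHF anterior and heat shock genes (0.0215) in lateral walls. Against non-failing hearts they were sarcomere genes in CRT anterior walls (0.0418), and wall stress (0.0108), sarcomere (0.0305) and heat shock genes (0.0361) in CRT lateral walls. The covariance of the DHF and CRT changes in the lateral wall less its simulated mean, 0.0314, was 0.0374 with the controls split.

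Of 184 called results of named genes 164 were kept with scan day as a block, 181 with quantile normalization, 143 with median scaling, 168 with normexp, 161 with the series values, 139 with no filter, 147 without the dogs of doubted arrays, 164 with the floor halved and 160 with it doubled. All 168 that had a probe in the stricter filter were kept. Over these alternatives 1595 of 1824 values kept their call, 229 lost it and 0 turned sign. Named genes were not followed with only the arms compared, where CRT minus DHF wall differences had 2 calls and DHF wall differences 172. Most genes named for CRT minus DHF wall differences thus cannot have kept their call there. Nor were named genes followed with array weights, trend and robust variance or the fits of all arrays together. Among genes not called, MYH7 in the DHF anterior wall turned from −0.04 to 0.034 with scan day as a block (adjusted p = 0.948), and PLN from −0.00 to 0.009 with median scaling and 0.001 with normexp.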

Other observations

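The test that the anterior wall departs further was chosen after the result was seen, and the test that CRT leaves part of the wall difference was set beforehand.

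Some lists did not shift although single members did. In the DHF anterior wall the collagen and matrix list had a median of −0.04 (adjusted p = 0.996) while CCN2 was higher by 1.73. The adhesion molecules VCAM1 and ICAM1 were higher by 1.52 and 0.91 and the chemokine CXCL12 lower at −0.85. The hydroxylase EGLN3 was higher by 0.79. In the CRT lateral wall the receptor FLT1 was lower at −0.77, while CCN2 was higher by 1.18 (not called without the dogs of doubted arrays), FHL1 by 1.37 and MYOM1 by 1.22.

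Lists that passed in none of the 12 comparisons with the settings used had these smallest adjusted p values, though some of them passed under an alternative. In the DHF anterior wall it was 0.287 for adrenergic and angiotensin genes and 0.107 for fibroblast markers. In the DHF lateral wall it was 0.0685 for cell cycle genes (0.0274 with scan day as a block), 0.0685 for erythroid, 0.315 for chamber endocardial markers and 0.157 for fatty acid oxidation. For the wall difference of CRT minus DHF it was 0.155 for calcium handling, 0.349 for apoptosis and 0.274 for nerve markers. For CRT minus non-failing it was 0.351 for smooth muscle and pericyte markers (0.0215 without the dogs of doubted arrays) and 0.539 for ion channels. In the CRT wall difference it was 0.181 for growth factors and 0.181 for inflammatory genes, in CRT against DHF lateral walls 0.184 for collagen and matrix (0.00458 without those dogs), and in CRT against non-failing anterior walls 0.57 for lymphocyte markers.

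In DHF dogs left out of the calling, the probes of the DHF wall difference departed from the non-failing mean 5.58 times as far in the anterior as in the lateral wall of DHF hearts. The lateral departure, −0.12 ± 0.20 (SD, n = 10), was not told apart from 0 (p = 0.0762, exact test over assignments of sign to the dogs). The ratio is therefore imprecise. In DHF hearts, genes such as XIRP2 and CRYAB may thus depart mainly in the anterior wall. For the 449 probes the mean wall difference in CRT minus non-failing hearts was −0.041 (exact permutation p = 0.692), so no remainder was seen in the mean. Single CRT dogs ran from −0.58 to 0.40 (SD 0.31) and single non-failing dogs from −0.23 to 0.10 (SD 0.12). The test of means thus does not show that the walls of each CRT dog were even. Both walls of CRT hearts still lay away from the non-failing mean, at −0.31 and −0.35. Against DHF the anterior wall lay nearer the non-failing mean by 0.376 (exact permutation p = 0.00694) and the lateral wall further from it by 0.23 (exact permutation p = 0.0272). Each DHF dog was measured on its own probe set and CRT dogs on the 449 probes, so a part of these differences may come from the probes. With that limit, both a return of the anterior and a shift of the lateral wall could contribute to the even walls in CRT.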
